A study of Mus musculus with 16 samples.

How the data were processed

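Gene expression was measured with a mouse Affymetrix 1-colour array in liver tissue of 8 transgenic mice on a C57BL/6J background, killed at 18 months of age. Per the labels' protocols, 4 mice expressed the c-MYC oncogene in liver under control sequences of woodchuck hepatitis virus, and the other 4 carried a REG3A transgene as well. From each mouse a tumour and a piece of non-tumour liver were dissected and snap frozen, which gave 16 arrays in 4 groups of 4. Total RNA was extracted with Trizol, and 200 ng per sample was turned into biotin-labelled single-strand cDNA, per the labels' protocols.

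The deposited table holds log2 expression values that the authors made with the RMA method in Affymetrix Expression Console 1.4.1, per the submitters' processing notes. RMA corrects the background, makes the distributions of the arrays equal and summarises the probes of each transcript into 1 value. The settings of that run and the base of the logarithm are not stated; log2 was read from the range of the values, which is what RMA gives by default. Quantile normalisation within RMA removes any global difference in RNA content between tumour and non-tumour liver, so every change is relative to the other genes on the array. Array means lay between 5.434 and 5.465, array medians between 4.896 and 4.973 and array maxima between 13.55 and 13.68. No detection calls came with the values, so signal over background is unknown for single genes, and the number of arrays limits the precision. No 2 arrays held identical values (0 pairs).

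The table has 41345 transcript rows. The platform annotation gave exactly 1 gene symbol to 23521 of them, several symbols to 1814, which were left unnamed, and none to 16010. By Entrez ID, 23328 of the rows with 1 symbol matched the RefSeq gene table of assembly GRCm38.p6, and 0 symbols changed. That table was used for names and for the chromosome of each gene; the build behind the array design is not stated, so no coordinates are given. The 22180 symbols included 1082 with more than 1 row, and the row with the highest mean over the 16 arrays stood for the gene. A gene was tested when its value exceeded the array's median over all rows in at least 4 of the 16 arrays, which left 13555 genes. Among genes called in the comparison of tumour with non-tumour liver, other rows of the same gene had the opposite sign in 25 of 316 cases in MYC mice and in 15 of 181 cases in MYC/REG3A mice.

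Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided) in fits over all 16 arrays, with Benjamini-Hochberg adjustment over the genes of a comparison and a threshold of 0.05. The comparisons of tumour with non-tumour liver, and the difference of these changes between genotypes, had the mouse as a block, since both samples of a mouse came from the same animal. Within genotype, the deviations of a mouse's tumour and non-tumour array from their group means correlated at 0.0963 to 0.325, all above 0, and 7 of the 8 mice had their highest correlation with their own tumour; the consensus within-mouse correlation was 0.101. The comparisons between genotypes used the 4 group means without a block, because the mice of the genotypes are different animals. Standard errors (SE) are those of limma, and n is 4 mice per genotype throughout. They rest on a residual spread per gene that is pooled over all groups, so they do not measure the spread within a single group. The p-values of limma rest on the same pooled spread. Group values are means ± SD.

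Gene lists were tested with camera in limma, with a preset correlation between genes of 0.01, 2-sided, adjusted over the lists of a comparison. The 42 lists cover MYC-related programmes, liver functions, inflammation, the REG family, sex-biased genes, markers of other cell types that dissected liver can hold, and handling of the tissue. Of these, 38 had at least 5 tested genes and were tested. Of the distinct list members, 734 had a gene row and 83 had none. With the correlation estimated from the data, 0 lists were called in any of the 5 comparisons. That estimate also takes in differences between the mice of a group. In simulated data a list with a known shift was recovered with either setting, in all 5 comparisons. Genes were drawn independently there, so this does not show how either setting handles genes that vary together.

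The comparisons, the lists and the rule for named genes were fixed before the data were examined. The rule named, per comparison, up to 10 genes with the largest rise and 10 with the largest fall among genes past the threshold whose direction held in all 4 mice or whose groups did not overlap. Where fewer passed, the genes of lowest unadjusted p were added up to 5 per direction. Predicted gene models and small RNAs were left out. It also named up to 4 members of lowest p in each list described, and always Myc, the REG family, Afp, Gpc3, Glul, Alb, Ogt, Oga, Gfpt1, Xist and Ddx3y. Ddx3y had no row with a single symbol, and other Y-linked genes were used for the check of sex. A human REG3A transcript cannot be read with certainty on a mouse array, so the genotype labels could not be checked on their gene.

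The fits were tested on simulated data with 13555 genes drawn from the means and spreads of the arrays. For the comparison of tumour with non-tumour liver in MYC mice, 76.1% of genes changed by 1 on the log2 scale and 17.9% of those changed by 0.5 were recovered; in MYC/REG3A mice these shares were 82.1% and 19.4%. Between genotypes, the fit recovered 89.6% and 40.3% in non-tumour liver and 74.6% and 20.9% in tumours. For the difference of the tumour changes it recovered 56.7% and 5.97%. Each simulated gene had the same spread in all groups. Differences of these shares between the genotypes, or between tumours and non-tumour liver, therefore reflect the random draw and not the arrays.

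The alternatives were no filter, a stricter filter at the array's 70th percentile (9168 genes), quantile normalisation again, median centring, the mean over all rows of a gene, moderation with trend and robust settings, array weights, the mouse left out as a block or taken as a random effect, a block across genotypes, only the arrays of a comparison, a fold threshold, each mouse left out in turn, an estimated correlation, and lists without shared members. After the data were seen, a fit without MYC/REG3A mice 2 and 4 and a fit with the level of clock genes as a covariate were added. A planned covariate for sex was not run, because the sex-linked genes did not separate the mice.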

Results

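Liver transcripts were measured with mouse arrays in 8 mice aged 18 months, 4 MYC mice and 4 MYC/REG3A mice. MYC mice express the c-MYC oncogene in the liver and develop liver tumours. MYC/REG3A mice carry in addition a transgene for REG3A, a secreted C-type lectin that pancreas and gut make and that diseased liver can express. Each mouse gave 1 tumour and 1 piece of non-tumour liver, so the 16 arrays form 4 groups of 4. The arrays had near-equal distributions, with mean log2 values of 5.434 to 5.465, and 13555 genes were tested. The first principal component held 49.2% of the variance and the second 9.79%. On the first, the non-tumour livers lay between -31 and -26.4 and 6 of the 8 tumours between 32.7 and 42.3. The tumours of MYC/REG3A mice 2 and 4 lay between them, at -4.21 and 2.55. Xist, which is transcribed from the inactive X chromosome, had a log2 level of 11.66 to 11.81 in all 8 non-tumour livers, and of 9.226 to 12.15 in the tumours, while Eif2s3y, Kdm5d, Uty and Usp9y from the Y chromosome lay between 2.89 and 3.69 on every array.

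The comparison of tumour with non-tumour liver in MYC mice asks which transcripts differ in the MYC tumours. Most tested transcripts with female-biased expression were lower in the tumours, 14 of 17 by limma, and most of the cell cycle (28 of 31) and of ribosome assembly (22 of 24) were higher. As whole lists these were called by camera only with the preset correlation: 17 lists were called with it and 0 with an estimated one. Cyp3a16, a cytochrome P450, fell by 7.09 on the log2 scale (SE 1.02, n = 4 mice, limma adjusted p = 0.0014). The sulfotransferases Sult2a2, Sult3a1 and Sult2a1 fell by 5.52, 5.45 and 4.89 (SE 0.598, 0.882 and 0.435), and Cyp2c69, Cyp3a44 and Cyp2b9 fell by 5.72, 4.59 and 4.56 (SE 0.694, 0.5 and 1.37). Slc22a26, an organic anion transporter, A1bg, a secreted plasma protein, and Mup3, a major urinary protein, fell by 6.17, 4.86 and 4.48 (SE 0.836, 1.2 and 0.608). The tumour means of Cyp3a16, Sult3a1 and Sult2a1, at 3.17, 3.14 and 3.44, lay below the lower quartile of every array (3.71 to 3.77). Background limits the fall that can be measured there, so their falls are lower bounds. Sult2a2 and Cyp2b9 lay below it in 1 of the 4 tumours, so their falls are lower bounds too. The largest rises were in Slc4a9, a bicarbonate transporter, at 3.69 (SE 0.683, adjusted p = 0.00381), in Slc35f2 at 3.34 (SE 0.233, adjusted p = 0.000221) and in Trpm6, a magnesium channel, at 3.08 (SE 0.446, adjusted p = 0.00143).

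Further rises in the MYC tumours included Elapor1 and Dctd, the deaminase of dCMP, both at 2.95 (SE 0.684 and 0.294), and Tmem45b at 2.89 (SE 0.332). Smpdl3b, AI506816 and Serpinb1a rose by 2.83, 2.79 and 2.74 (SE 0.45, 0.264 and 0.451). Igf2bp3, an RNA-binding protein of fetal tissue, rose by 2.76 (SE 0.723). The tumours of MYC mice 1 and 4 spanned 9.60 to 5.63 for this gene, and without MYC mouse 1 it no longer passed. Each of these genes changed the same way in all 4 mice. In total 4505 of 13555 genes passed limma's threshold, 2357 higher and 2148 lower, and 985 of them changed by at least 1 on the log2 scale, 548 higher and 437 lower. Without MYC mouse 4 the count was 2975 and A1bg did not pass, and Cyp2b9 did not pass without MYC mouse 1, 3 or 4.

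Among the preset lists, 22 of 24 tested ribosome biogenesis genes rose in the MYC tumours and 0 fell, with a median change of 1.12 (camera adjusted p = 3.47e-14; adjusted p = 0.535 with an estimated correlation). Nop56, a nucleolar protein of box C/D particles, rose by 1.96 (SE 0.22), Srm, the spermidine synthase, by 1.60 (SE 0.172), Polr1b, a subunit of RNA polymerase I, by 1.43 (SE 0.129) and Wdr43 by 1.17 (SE 0.123). Of 31 cell cycle genes, 28 rose and 1 fell (median 1.37, camera adjusted p = 8.31e-13; adjusted p = 0.535 with an estimated correlation). Ccnb2 and Ccna2, cyclins of mitosis and S phase, rose by 2.39 and 2.08 (SE 0.291 and 0.274), Top2a by 1.60 (SE 0.189) and Mcm2, a part of the replicative helicase, by 1.36 (SE 0.165). Of 26 genes of oxidative phosphorylation, 14 rose and 0 fell (median 0.43, camera adjusted p = 1.13e-05; adjusted p = 0.535 with an estimated correlation), among them Cyc1 at 0.92 (SE 0.162), Cox7a2 at 0.81 (SE 0.129), Ndufb5 at 0.69 (SE 0.132) and Uqcrc1 at 0.63 (SE 0.123).

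Several lists of hepatocyte functions were called as lower in the MYC tumours with the preset correlation, and none with an estimated one. Of 17 female-biased genes 14 fell and 0 rose (median -4.28, camera adjusted p = 3.9e-07), and of 17 genes of cholesterol synthesis 13 fell and 0 rose (median -1.05, camera adjusted p = 1.35e-06). Tm7sf2, Pmvk, Msmo1 and Lss of that pathway fell by 1.91, 1.68, 1.51 and 1.19 (SE 0.283, 0.274, 0.28 and 0.229). Of 19 pericentral and Wnt target genes 13 fell and 0 rose (median -1.27, camera adjusted p = 3.23e-05), with falls of 2.70 in Cyp1a2 (SE 0.525), 2.20 in Slc1a2 (SE 0.509), 1.62 in Tbx3 (SE 0.367) and 1.09 in Nkd1, a feedback inhibitor of Wnt signalling (SE 0.181). Glul, the glutamine synthetase of pericentral hepatocytes, fell by 1.91 (SE 0.615, adjusted p = 0.0384), a call that was lost without any 1 of the 4 MYC mice. Of 30 cytochrome P450 and xenobiotic genes 16 fell and 2 rose (median -0.64, camera adjusted p = 4.6e-05). Among them Cyp4f14, Cyp2c37, Ces1d and Cyp2c29 fell, with log2 changes of -3.97, -2.32, -1.86 and -1.80 (SE 0.467, 0.332, 0.175 and 0.275). Of 20 genes of fatty acid synthesis 11 fell and 0 rose (median -0.61, camera adjusted p = 0.000204), with falls of 3.24 in Acacb (SE 0.474), 1.73 in Acss2 (SE 0.254), 0.997 in Thrsp (SE 0.206) and 0.73 in Acaca (SE 0.149). For each of these 5 lists adjusted p = 0.535 with an estimated correlation. Other lists of hepatocyte functions had no call, namely the urea cycle (median -0.16, camera adjusted p = 0.478), gluconeogenesis and glycogen (median -0.13, adjusted p = 0.225), bile acids (median -0.25, adjusted p = 0.225), periportal genes (median -0.25, adjusted p = 0.732) and fatty acid oxidation (median -0.09, adjusted p = 0.563).

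Of 26 tested genes for secreted proteins of the hepatocyte, 6 fell and 1 rose in the MYC tumours (median -0.18, camera adjusted p = 0.00703; adjusted p = 0.535 with an estimated correlation), with falls of 2.34 in C8a (SE 0.441), 1.08 in F9 (SE 0.175), 0.91 in F11 (SE 0.228) and 0.82 in Cfb (SE 0.141). Alb, the albumin gene, differed by -0.16 (SE 0.089, adjusted p = 0.187). Its level of 13.52 in non-tumour liver was close to the array maxima of 13.55 to 13.68, where the scale limits what can be seen. Of 23 acute phase genes 9 fell and 0 rose (median -0.35, camera adjusted p = 0.00968; adjusted p = 0.535 with an estimated correlation). Saa2 fell by 3.05 (SE 0.428), Crp by 1.36 (SE 0.291), Steap4 by 1.05 (SE 0.194) and Socs3 by 1.02 (SE 0.21). Without the mouse block this last list and that of neutrophil markers were not called.

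Lists of markers of 5 other liver cell types were called as lower in the MYC tumours with the preset correlation, and 0 with an estimated one. Those of T cells, NK cells, other vascular endothelium and bile duct cells were not called. Of 16 sinusoidal endothelial markers 14 fell and 0 rose (median -1.03, camera adjusted p = 8.86e-08), among them Rspo3 by 2.06 (SE 0.26), Tek by 1.17 (SE 0.141), Stab2 by 1.15 (SE 0.139) and Kdr by 1.01 (SE 0.128). Of 20 macrophage and Kupffer cell markers 11 fell and 0 rose (median -0.71, camera adjusted p = 6.29e-05). Folr2, Clec4f, Timd4 and Cd163 fell by 2.33, 1.85, 1.76 and 1.23 (SE 0.393, 0.357, 0.259 and 0.129). B and plasma cell markers (4 of 11 fell, median -0.57) and neutrophil markers (5 of 9 fell, median -0.53) were both called at a camera adjusted p of 0.0112. Jchain, Ighm, Cd79a and Pou2af1 fell by 2.74, 2.57, 1.01 and 0.86 (SE 0.675, 0.668, 0.263 and 0.216), and Retnlg, Csf3r, Mmp9 and Hdc by 0.88, 0.87, 0.68 and 0.53 (SE 0.278, 0.223, 0.143 and 0.131). For these 4 lists adjusted p = 0.535 with an estimated correlation. Of 21 stellate cell and matrix genes 9 fell and 0 rose (median -0.33, camera adjusted p = 0.0212; adjusted p = 0.614 with an estimated correlation), with falls of 2.10 in Reln, 1.93 in Hhip, 1.76 in Dpt and 1.06 in Des (SE 0.394, 0.147, 0.32 and 0.185). Hhip lay below the lower quartile of every array in 3 of the 4 tumours and Retnlg in 1, so their falls are lower bounds.

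Of 14 genes of antigen presentation 7 fell and 0 rose in the MYC tumours (median -0.37, camera adjusted p = 0.0115; adjusted p = 0.542 with an estimated correlation). H2-K1, Tap2, Psmb8 and Tapbp fell by 0.96, 0.91, 0.91 and 0.61 (SE 0.14, 0.177, 0.147 and 0.135). Of 26 interferon response genes 5 fell and 1 rose (median -0.42, camera adjusted p = 0.0172; adjusted p = 0.658 with an estimated correlation), with falls of 1.35 in Gbp3, 1.08 in Rtp4 and 0.63 in Stat2 (SE 0.27, 0.205 and 0.156) and a rise of 0.88 in Usp18, which restrains interferon signalling (SE 0.228). Without MYC mouse 1 the calls of the neutrophil, stellate cell, antigen presentation and interferon lists were lost, and without MYC mouse 4 that of the interferon list. Lists without a call included markers of T cells (median -0.25, camera adjusted p = 0.0549), NK cells (median -0.06, adjusted p = 0.854), other vascular endothelium (median -0.10, adjusted p = 0.854), bile duct and progenitor cells (median -0.36, adjusted p = 0.136) and adipose tissue (median 1.17, adjusted p = 0.0752). Within the vascular list Esm1, a marker of endothelial tip cells, rose by 2.46 (SE 0.252) and Angpt2 by 1.06 (SE 0.334), while Plvap fell by 1.12 (SE 0.215) and Vwf by 0.52 (SE 0.154).

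**Figure D1:**
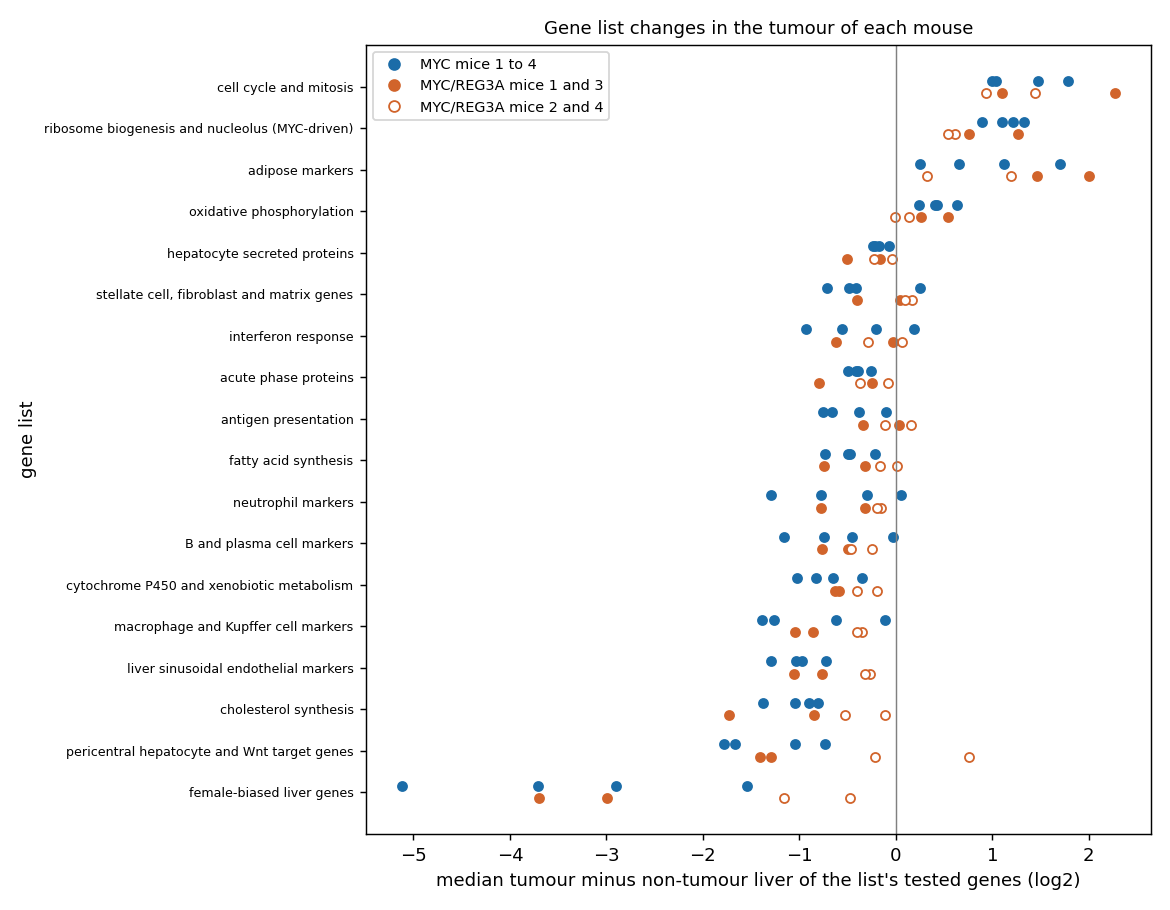
Median tumour minus non-tumour change (log2) of the tested genes of each list called in either genotype, with 1 point per mouse. Cell cycle medians are above 0.9 in all 8 mice, and female-biased medians run from -5.12 in MYC mouse 4 to -0.472 in MYC/REG3A mouse 2, whose points, like those of mouse 4, are open circles.

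The same comparison in MYC/REG3A mice asks which transcripts differ in tumours that carry both transgenes. Most tested cell cycle (28 of 31) and ribosome assembly transcripts (20 of 24) were again higher by limma, 7 of 17 female-biased transcripts were lower, and 2 of 5 adipose markers were higher. As whole lists these were called by camera only with the preset correlation, with which 15 lists were called, against 0 with an estimated one. Anxa13 rose by 3.72 (SE 0.87, n = 4 mice, limma adjusted p = 0.0258), Ccnb2 by 3.27 (SE 0.291, adjusted p = 0.00227) and Elapor1 by 3.01 (SE 0.684, adjusted p = 0.0235). Fabp4, a fatty acid binding protein of adipocytes, macrophages and some endothelium, rose by 2.73 (SE 0.449), Slc35f2 by 2.61 (SE 0.233), Plk1, a kinase of mitosis, by 2.59 (SE 0.333) and Ly6d by 2.57 (SE 0.634). Rbm24, Zfas1 and Tmem45b rose by 2.53, 2.49 and 2.45 (SE 0.35, 0.253 and 0.332). The largest falls were 4.10 in Cyp3a16 (SE 1.02, adjusted p = 0.0312), 3.89 in Sult3a1 (SE 0.882), 3.41 in Slc22a26 (SE 0.836) and 3.06 in Cyp2c69 (SE 0.694). These SE pool the spread of both genotypes. The tumour SDs of Cyp3a16, Sult3a1 and Slc22a26 were 3.77, 3.02 and 3.03 in MYC/REG3A mice and 0.323, 0.199 and 0.371 in MYC mice. Cxcl13, a chemokine that attracts B cells, fell by 2.78 (SE 0.656), and Sult2a3, Cyp3a44, Slc22a27, Mup-ps12 and Rdh16f2 by 2.63, 2.62, 2.62, 2.60 and 2.55 (SE 0.693, 0.5, 0.619, 0.667 and 0.641). Mup-ps12 lay below the lower quartile of every array in 3 of the 4 tumours, and Cyp3a16 and Sult3a1 in 2, so these 3 falls are lower bounds. All genes named here moved the same way in all 4 mice.

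In MYC/REG3A mice 1690 genes passed limma's threshold, 1028 higher and 662 lower, and 388 of them changed by at least 1 on the log2 scale, 261 higher and 127 lower. The tumours of these mice were unequal. The SD of the change over the tested genes was 0.679 and 0.657 in mice 1 and 3, and 0.336 and 0.429 in mice 2 and 4, against 0.624 to 0.729 in the MYC mice. The count of called genes rested on mice 1 and 3: it was 281 without mouse 1, 273 without mouse 3 and 944 without mouse 4, and 1359 without mice 2 and 4 together. Of the 281 genes 247 were higher and 34 lower, and of the 273 genes 240 and 33. With the clock gene level as a covariate, an alternative chosen after the data were seen, 232 genes passed, 210 higher and 22 lower. Of the 20 genes named above, the 10 with the largest falls and Anxa13, Elapor1 and Ly6d lost their call both without mouse 1 and without mouse 3, and Fabp4 lost it without mouse 3.

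Of 31 cell cycle genes 28 rose and 0 fell in the MYC/REG3A tumours (median 1.43, camera adjusted p = 4.55e-21; adjusted p = 0.54 with an estimated correlation), with rises of 2.13 in Ccna2 (SE 0.274), 1.5 in Top2a (SE 0.189) and 1.4 in Mcm2 (SE 0.165). The list's median change was 2.27, 0.932, 1.1 and 1.44 in mice 1 to 4. Of 24 ribosome biogenesis genes 20 rose and 0 fell (median 0.81, camera adjusted p = 5.11e-15; adjusted p = 0.532 with an estimated correlation), with rises of 1.48 in Nop56 (SE 0.22), 1.23 in Ppan (SE 0.186), 0.87 in Wdr43 (SE 0.123) and 0.86 in Polr1b (SE 0.129). Of 26 genes of oxidative phosphorylation 2 rose and 0 fell (median 0.22, camera adjusted p = 0.00116; adjusted p = 0.616 with an estimated correlation), namely Cyc1 by 0.66 (SE 0.162) and Cox7a2 by 0.50 (SE 0.129). Of 5 tested adipose markers 2 rose and 0 fell (median 1.39, camera adjusted p = 0.0073; adjusted p = 0.532 with an estimated correlation), Fabp4 and, by 1.39, Plin4, a coat protein of lipid droplets (SE 0.324). Cidec, another lipid droplet protein, differed by 2.30 (SE 0.863) without passing, at an adjusted p of 0.107. Over the list alone 4 of the 5 passed. Fabp4 also rose in the MYC tumours, by 1.88 (SE 0.449).

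Several lists of hepatocyte functions were called as lower in the MYC/REG3A tumours with the preset correlation, and none with an estimated one. Of 17 cholesterol synthesis genes 6 fell and 0 rose (median -0.81, camera adjusted p = 4.95e-07), and 15 fell when adjusted over the list alone. Cyp51, Tm7sf2, Lss and Mvk fell by 1.44, 1.10, 1.05 and 0.88 (SE 0.353, 0.283, 0.229 and 0.2). Of 17 female-biased genes 7 fell and 0 rose (median -2.09, camera adjusted p = 7.62e-06), including Sult2a1 by 2.42 (SE 0.435) and Cux2, a transcription factor of female liver, by 0.76 (SE 0.171). Their median change was -2.99 and -3.7 in mice 1 and 3 and -0.472 and -1.16 in mice 2 and 4. Of 23 acute phase genes 6 fell and 0 rose (median -0.42, camera adjusted p = 0.00068), with falls of 1.81 in Saa2, 0.89 in Steap4, 0.66 in Saa4 and 0.54 in Orm1 (SE 0.428, 0.194, 0.146 and 0.134). Of 26 hepatocyte secreted proteins 4 fell and 1 rose (median -0.21, camera adjusted p = 0.000814), with falls of 0.82 in F9, 0.72 in Serpina1a and 0.70 in Cfb and a rise of 0.51 in Apoa4 (SE 0.175, 0.172, 0.141 and 0.117). Of 30 cytochrome P450 and xenobiotic genes 3 fell and 0 rose (median -0.39, camera adjusted p = 0.00516), namely Ugt2b1 by 1.18, Cyp3a13 by 0.85 and Cyp2c70 by 0.59 (SE 0.291, 0.147 and 0.126). For these 5 lists adjusted p = 0.54 with an estimated correlation.

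Of 20 genes of fatty acid synthesis 3 fell and 0 rose in the MYC/REG3A tumours (median -0.30, camera adjusted p = 0.00738; adjusted p = 0.577 with an estimated correlation), namely Acss2 by 1.06, Thrsp by 0.79 and Acaca by 0.61 (SE 0.254, 0.206 and 0.149). The 19 pericentral and Wnt target genes had a median of -0.52 (camera adjusted p = 0.0226; adjusted p = 0.794 with an estimated correlation), and 0 of them passed singly by limma. Their median was -1.41 and -1.29 in mice 1 and 3, -0.219 in mouse 2 and 0.763 in mouse 4. The call was lost without mouse 1 or without mouse 3. Those of oxidative phosphorylation, fatty acid synthesis and neutrophil markers were lost without mouse 1, the last 2 also without the mouse block. Not called were the urea cycle (median -0.24, camera adjusted p = 0.0609), gluconeogenesis and glycogen (median -0.13, adjusted p = 0.506), bile acids (median -0.20, adjusted p = 0.255), periportal genes (median -0.31, adjusted p = 0.146) and fatty acid oxidation (median 0.24, adjusted p = 0.0609). The median of this last list was 0.608, -0.0766, -0.23 and 0.661 in mice 1 to 4.

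Of 20 macrophage and Kupffer cell markers 9 fell and 0 rose in the MYC/REG3A tumours (median -0.66, camera adjusted p = 3.04e-05), with falls of 1.92 in Clec4f, 1.63 in Timd4, 1.61 in Cd5l and 0.72 in Cd163 (SE 0.357, 0.259, 0.297 and 0.129). Of 16 sinusoidal endothelial markers 10 fell and 1 rose (median -0.60, camera adjusted p = 3.62e-05). Clec4g, Rspo3 and Mrc1 fell by 1.48, 1.15 and 0.92 (SE 0.331, 0.26 and 0.182), and Flt4, the receptor of VEGF-C, rose by 1.41 (SE 0.31). Of 11 B and plasma cell markers 3 fell and 0 rose (median -0.49, camera adjusted p = 0.00379), namely Jchain by 2.38, Cd79b by 0.98 and Cd79a by 0.95 (SE 0.675, 0.275 and 0.263). For these 3 lists adjusted p = 0.54 with an estimated correlation. The 9 neutrophil markers had a median of -0.35 (camera adjusted p = 0.0358; adjusted p = 0.616 with an estimated correlation), with 0 members past limma's threshold. Lists without a call included stellate cell and matrix genes (median -0.02, camera adjusted p = 0.774), other vascular endothelium (median 0.16, adjusted p = 0.401), T cells (median -0.13, adjusted p = 0.145), NK cells (median -0.08, adjusted p = 0.661), bile duct and progenitor cells (median -0.08, adjusted p = 0.885), interferon response (median -0.25, adjusted p = 0.0978) and antigen presentation (median -0.12, mean 0.03, adjusted p = 0.774). Esm1 and Emcn of the vascular list rose by 1.26 and 1.19 (SE 0.252 and 0.257).

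The tumour changes of the genotypes shared direction. Of the called genes, 938 were higher in the tumours of both genotypes, where 179 would overlap if the calls were independent, 595 were lower in both, against 105, and 0 were called in opposite directions, against 278. The comparisons share no arrays, although they share the estimate of spread. Across genes, which are not independent replicates, the changes correlated at r = 0.872 and rho = 0.839. Of the genes called in MYC mice 97.9% had the same sign in MYC/REG3A mice and 89.7% had a smaller change there. Choosing genes by their call in MYC mice favours large changes in those mice. Of the 1690 genes called in MYC/REG3A mice 66.3% had a smaller change there than in MYC mice, with a median ratio of 0.862. Over all tested genes the share was 67.3%, and the SD of the mean change was 0.438 in MYC/REG3A and 0.589 in MYC mice. In mice 2 and 4 of the MYC/REG3A genotype the genes that rose by at least 1 in MYC tumours had medians of 0.714 and 0.653, and in mice 1 and 3 medians of 1.37 and 1.13.

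**Figure D2:**
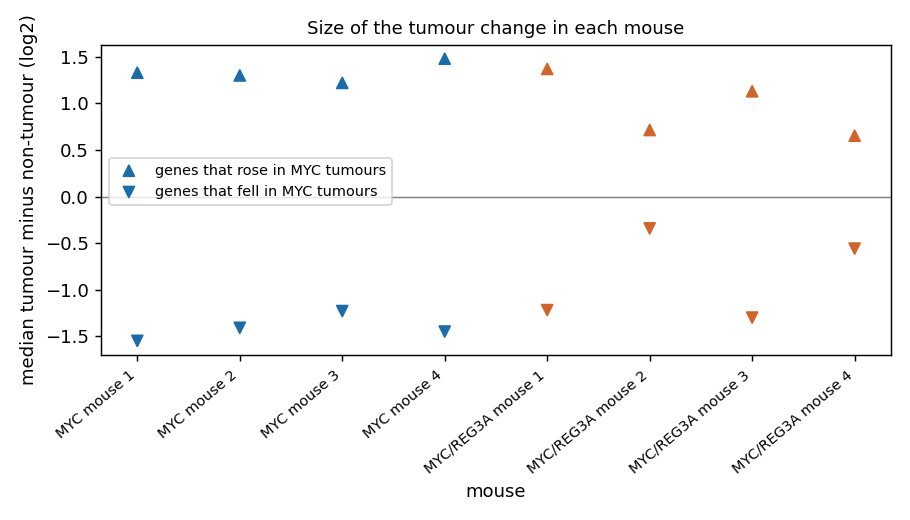
Median tumour minus non-tumour change (log2) in each of the 8 mice of the 548 genes that rose (upward triangles) and the 437 that fell (downward triangles) by at least 1 in the MYC tumours. The genes were chosen in the MYC mice. MYC/REG3A mice 2 and 4 have the medians nearest to 0, at 0.714 and 0.653 for the genes that rose and -0.342 and -0.559 for those that fell.

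The comparison of non-tumour liver between genotypes asks what the REG3A transgene goes with outside the tumours. No single gene passed, and the lists that were called had higher urea cycle and periportal transcripts and lower matrix, endothelial, macrophage and immediate early transcripts in MYC/REG3A mice. The 14 lists were called with the preset correlation, and 0 with an estimated one. Of the 35 splits of the 8 livers into 4 and 4, 13 gave at least as many lists. The count by limma was 0 of 13555, with a lowest adjusted p of 0.904 and 739 genes, or 5.45%, at an unadjusted p under 0.05. The genes of lowest p, none past the threshold, were Gorasp1 (0.50), Sult5a1 (0.97), Dhrs11 (0.48), Pgpep1 (0.47) and Atp6v1e1 (0.33) on the higher side and Flt1 (-0.63), Elk3 (-0.45), Enpp6 (-0.61), F2r, a thrombin receptor (-0.82), and F2rl2 (-0.43) on the lower side, as log2 differences of MYC/REG3A minus MYC with SE between 0.0859 and 0.255. Without MYC mouse 2 the count was 22.

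In non-tumour liver, the list of the urea cycle and amino acid catabolism had 21 of 22 genes higher in MYC/REG3A mice (median 0.35, camera adjusted p = 1.16e-10; adjusted p = 0.102 with an estimated correlation). Agxt, an aminotransferase of glyoxylate, differed by 1.34 (SE 0.372), Gnmt by 0.52 (SE 0.19), Aldh4a1 by 0.45 (SE 0.142) and Hgd by 0.22 (SE 0.0835). All 26 genes of oxidative phosphorylation lay higher by a small amount (median 0.10, camera adjusted p = 0.000311; adjusted p = 0.743 with an estimated correlation), as did 11 of 14 periportal genes (median 0.23, camera adjusted p = 0.016; adjusted p = 0.67 with an estimated correlation), with Hal at 0.63 (SE 0.269) and Cps1, the first enzyme of the urea cycle, at 0.26 (SE 0.122). On the lower side, 20 of 21 stellate cell and matrix genes had a median of -0.45 (camera adjusted p = 1.53e-10; adjusted p = 0.382 with an estimated correlation), with Postn at -0.86 (SE 0.309), Col6a3 at -0.64 (SE 0.199), Des at -0.51 (SE 0.196) and Sparc at -0.45 (SE 0.164). Of 21 immediate early and dissection stress genes 18 lay lower (median -0.32, camera adjusted p = 4.29e-06; adjusted p = 0.102 with an estimated correlation), and 4 passed when adjusted over the list alone. Atf3, Jun, Klf2 and Fos of this list differed by -0.98, -0.97, -0.54 and -0.36 (SE 0.271, 0.282, 0.16 and 0.117).

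Also lower in the non-tumour liver of MYC/REG3A mice were the lists of sinusoidal endothelium (15 of 16 genes, median -0.31, camera adjusted p = 6.48e-06), macrophages (19 of 20, median -0.43, adjusted p = 7.84e-06), neutrophils (9 of 9, median -0.46, adjusted p = 1.87e-05) and other vascular endothelium (8 of 10, median -0.37, adjusted p = 0.000666). For these 4 lists adjusted p = 0.569 with an estimated correlation. The mean level of macrophage markers was 7.664 in MYC mouse 2 and 8.454 to 9.031 in the other MYC livers, against 7.764 to 8.326 in MYC/REG3A livers. That of neutrophil markers was 5.157 in MYC mouse 2 and 6.231 to 6.413 in the other MYC livers, against 5.005 to 5.966. Lyve1 differed by -1.05 (SE 0.311), Vwf by -0.83 (SE 0.318), Ccr2, a receptor of recruited monocytes, by -0.75 (SE 0.275), Ctss by -0.73 (SE 0.255) and Retnlg by -1.21 (SE 0.561). Cell cycle genes (27 of 31 lower, median -0.28, camera adjusted p = 0.000261) and antigen presentation genes (13 of 14, median -0.19, camera adjusted p = 0.00964) followed, with an adjusted p = 0.746 and an adjusted p = 0.743 with an estimated correlation. Glycolysis genes (16 of 19 lower, median -0.15) and bile duct markers (11 of 12, median -0.24) were called at a camera adjusted p of 0.016, and interferon response genes (22 of 26, median -0.15) at 0.0473. These 3 lists had adjusted p = 0.569, adjusted p = 0.67 and adjusted p = 0.782 with an estimated correlation. Ccnb2 differed by -0.84 (SE 0.326), Pkm by -0.58 (SE 0.198), Krt19 by -0.28 (SE 0.129), Ciita by -0.31 (SE 0.151) and Oas3 by -0.46 (SE 0.234). Markers of T cells (median -0.09, camera adjusted p = 0.371), NK cells (median -0.20, adjusted p = 0.69), B cells (median -0.04, adjusted p = 0.765) and adipose tissue (median -0.16, adjusted p = 0.765) had no call. The calls of the glycolysis, antigen presentation, interferon and bile duct lists were lost without MYC mouse 1, and those of oxidative phosphorylation and interferon without MYC mouse 4. Those of bile duct and interferon were lost without MYC/REG3A mouse 2, those of glycolysis and interferon without MYC/REG3A mouse 1, and further ones without MYC mouse 3 (glycolysis), MYC/REG3A mouse 3 (bile duct) or mouse 4 (interferon). The periportal call was lost without MYC mouse 3, MYC mouse 4 or MYC/REG3A mouse 2, and with repeated quantile normalisation or median centring. Without MYC/REG3A mice 2 and 4 the calls of periportal genes (median 0.121) and antigen presentation (-0.159) were lost. The interferon list had a median of 0.00403 there without a call, and the other 11 lists kept their call.

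The comparison of tumours between genotypes asks how tumours that carry REG3A differ from those that do not. Between the tumours 3 genes passed limma's threshold. This count was 114 without MYC/REG3A mouse 1, 21 without MYC mouse 2 and 13 without MYC mouse 3. Gas1, a membrane protein that arrests growth, was higher by 0.87 (SE 0.109, n = 4 per genotype, limma adjusted p = 0.00344), with 5.89 ± 0.136 in MYC/REG3A tumours and 5.02 ± 0.143 in MYC tumours. Lpcat4, an acyltransferase of lysophospholipids, was lower by a log2 difference of -2.11 (SE 0.257, adjusted p = 0.00344), with 5.96 ± 0.513 against 8.07 ± 0.322. Trim43c was lower by -1.78 (SE 0.201, adjusted p = 0.00273), with 4.89 ± 0.316 against 6.66 ± 0.412. Among genes that did not pass, Mme, the neprilysin peptidase, had 9.56 ± 0.215 in MYC/REG3A tumours and 6.48 ± 1.1 in MYC tumours, a difference of 3.09 (SE 0.541), and Gask1a, Cyp4f15 and Acer2 differed by 1.20, 1.02 and -0.82, all at an adjusted p of 0.0739. Sult2a2 differed by 4.34 (adjusted p = 0.103), a lower bound since 1 MYC tumour lay below the lower quartile of every array, Sh3pxd2b by -0.67 (adjusted p = 0.0743) and Phykpl by -0.67 (adjusted p = 0.0981). At an unadjusted p under 0.05 there were 1437 genes, or 10.6%. This share is not a measure of genotype effects, since the fit pools the spread of the tumours with that of non-tumour liver. Arrays of a group were less alike in tumours (lowest r 0.9446) than in non-tumour liver (lowest r 0.9684), so p between tumours can be too small. The 3 calls were lost with only the tumour arrays in the fit and without MYC/REG3A mice 2 and 4, where the differences of Gas1, Lpcat4 and Trim43c were 0.85, -1.74 and -1.59.

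Several lists of hepatocyte functions lay higher in the tumours of MYC/REG3A mice. Of the 13 lists called here, 0 were called with an estimated correlation. Of the 35 splits of the 8 tumours, 15 gave at least as many lists. All 19 pericentral and Wnt target genes were higher (median 0.66, camera adjusted p = 7.66e-08; adjusted p = 0.633 with an estimated correlation), with 4 past the threshold over the list alone and 0 over all genes. Oat differed by 2.07 (SE 0.481), Cyp1a2 by 1.81 (SE 0.6), Nkd1 by 0.70 (SE 0.237) and Cyp2e1 by 0.66 (SE 0.194). Of 17 female-biased genes 16 were higher (median 1.74, camera adjusted p = 7.66e-08), of 30 cytochrome P450 genes 25 (median 0.41, camera adjusted p = 3.55e-06) and of 22 urea cycle genes 19 (median 0.28, camera adjusted p = 3.95e-05). For these 3 lists adjusted p = 0.564 with an estimated correlation. Sult2a1 differed by 3.40 (SE 0.811), Cyp4f14 by 2.59 (SE 0.574), Cyp2c29 by 1.41 (SE 0.356) and Prodh by 0.69 (SE 0.176). Sult2a1 lay below the lower quartile of every array in 3 of the 4 MYC tumours, so its difference is a lower bound. Of 24 genes of fatty acid oxidation 22 were higher (median 0.27, camera adjusted p = 3.95e-05; adjusted p = 0.799 with an estimated correlation), with Ehhadh at 1.34 (SE 0.375). Cholesterol synthesis (15 of 17 higher, median 0.23, camera adjusted p = 0.0149), antigen presentation (12 of 14, median 0.16, adjusted p = 0.0244), fatty acid synthesis (16 of 20, median 0.22, adjusted p = 0.0345) and sinusoidal endothelium (12 of 16, median 0.17, adjusted p = 0.044) were called as higher, with an adjusted p = 0.813 with an estimated correlation for each. Without MYC/REG3A mice 2 and 4 the median of cholesterol synthesis was -0.27 and that of sinusoidal endothelium -0.271, both called as lower. Those of fatty acid synthesis and antigen presentation were -0.209 and 0.0629 there, without a call. Periportal genes (median 0.01, camera adjusted p = 0.645), gluconeogenesis and glycogen (median 0.06, adjusted p = 0.919), bile acids (median 0.20, adjusted p = 0.0979) and hepatocyte secreted proteins (median 0.04, adjusted p = 0.141) had no call.

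Ribosome biogenesis lay lower in the MYC/REG3A tumours than in the MYC tumours, in 23 of 24 genes (median -0.41, camera adjusted p = 3.2e-09; adjusted p = 0.564 with an estimated correlation), with Nop16 and Polr1b at -0.50 (SE 0.172 for both), Wdr43 at -0.47 (SE 0.141) and Mybbp1a at -0.44 (SE 0.131). So did 12 of 17 p53 targets (median -0.13, camera adjusted p = 0.0157; adjusted p = 0.564 with an estimated correlation), with Plk2 at -0.57 (SE 0.133), 16 of 19 glycolysis genes (median -0.13, camera adjusted p = 0.0288; adjusted p = 0.734 with an estimated correlation), with Pfkp at -1.38 (SE 0.379), and 15 of 20 macrophage markers (median -0.38, camera adjusted p = 0.044; adjusted p = 0.813 with an estimated correlation), with C1qb at -0.63 (SE 0.253). Cell cycle genes (median -0.14, camera adjusted p = 0.211), neutrophil markers (median -0.56, adjusted p = 0.0765), stellate cell and matrix genes (median -0.11, adjusted p = 0.438) and the markers of T cells (median 0.03, adjusted p = 0.727), NK cells (median -0.20, adjusted p = 0.438), B cells (median 0.09, adjusted p = 0.438), bile duct cells (median 0.04, adjusted p = 0.548), other vascular endothelium (median -0.08, adjusted p = 0.483) and adipose tissue (median 0.13, adjusted p = 0.483) had no call. Without MYC/REG3A mice 2 and 4, 4 of the 13 lists kept their call, namely the urea cycle (median 0.298), cytochrome P450 (0.252), fatty acid oxidation (0.216) and macrophage markers (-0.521). Pericentral genes (-0.111), female-biased genes (0.00394), ribosome biogenesis (-0.135), glycolysis (-0.143) and p53 targets (-0.18) were not called there. Single mice decided the calls of fatty acid synthesis (lost without MYC mouse 2 or 4 or MYC/REG3A mouse 2 or 4), cholesterol synthesis (MYC/REG3A mouse 2 or 4), sinusoidal endothelium (MYC mouse 2 or 3 or MYC/REG3A mouse 2 or 4), antigen presentation (MYC mouse 3 or 4 or MYC/REG3A mouse 2 or 3), glycolysis (MYC mouse 2 or 3 or MYC/REG3A mouse 2 or 3), p53 targets (MYC mouse 2 or 3) and macrophages (MYC mouse 3 or MYC/REG3A mouse 1 or 3).

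The difference of the tumour changes between genotypes was tested directly with the mouse as a block. Trim43c was higher in the tumour by 1.83 to 2.5 in each MYC mouse and by 0.0650 to 0.610 in the MYC/REG3A mice, a difference of -1.87 (SE 0.197, n = 4 mice per genotype, limma adjusted p = 0.0412), and was the 1 gene past the threshold. Mme (3.32, SE 0.408, adjusted p = 0.0801) and Lpcat4 (-1.85, SE 0.24, adjusted p = 0.0851) followed without passing. Gask1a differed by 1.54 (adjusted p = 0.614), and Ces1d, Inhba, Tpbgl, Zfp296, Phykpl and Spatc1l by 1.28, 1.10, 1.15, -0.88, -0.87 and -1.30, all at an adjusted p of 0.873. At an unadjusted p under 0.05 there were 756 genes, or 5.58%. The call of Trim43c was lost in 7 of the 8 fits that left out 1 mouse, the exception being MYC/REG3A mouse 1.

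The tumour change was called as different between genotypes in 14 lists with the preset correlation, and in 0 with an estimated one. Of the 35 splits of the mice, 15 gave at least 14 lists. Of the 14 lists, 9 were called the same way between the tumours, and 6 were called the opposite way in non-tumour liver. These 6 were oxidative phosphorylation, antigen presentation, sinusoidal endothelium, stellate cell, bile duct and immediate early genes. Only antigen presentation and sinusoidal endothelium were called in both. The change of ribosome biogenesis was smaller in MYC/REG3A mice (median difference -0.295, 24 of 24 genes, camera adjusted p = 2.83e-07), with Polr1b at -0.57 (SE 0.182) and Srm at -0.69 (SE 0.243). So was that of oxidative phosphorylation (-0.22, 25 of 26 genes, camera adjusted p = 0.000332). The fall was smaller for sinusoidal endothelial markers (0.442, 16 of 16 genes, adjusted p = 1.71e-07), with Tek at 0.55 (SE 0.199), Stab2 at 0.56 (SE 0.196) and Kdr at 0.52 (SE 0.181), for pericentral genes (0.683, 19 of 19, adjusted p = 1.17e-05), female-biased genes (1.3, 15 of 17, adjusted p = 6.76e-06) and antigen presentation (0.476, 13 of 14, adjusted p = 1.61e-05), with Psmb8 at 0.74 (SE 0.208). With an estimated correlation none of these was called: pericentral genes had an adjusted p = 0.616 with an estimated correlation, oxidative phosphorylation an adjusted p = 0.722 with an estimated correlation, and the other 4 lists an adjusted p = 0.572 with an estimated correlation. Without MYC/REG3A mice 2 and 4 the medians were -0.125 for ribosome biogenesis, -0.0464 for oxidative phosphorylation, 0.133 for sinusoidal endothelium, -0.0116 for pericentral and 0.0304 for female-biased genes, all without a call. Antigen presentation kept its call at 0.293. Of all 14 lists called for this difference 3 kept their call there.

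Some genes and lists of interest passed in 1 of the 5 comparisons or in none. Myc, whose row reads the mouse transcript and was not shown to separate it from that of the transgene, fell by 0.59 in the MYC tumours (SE 0.127, adjusted p = 0.00673), from 7.68 to 7.09, a call that was lost without the mouse block, and differed by -0.14 in the MYC/REG3A tumours (SE 0.127, adjusted p = 0.486). Of the fetal and tumour markers Afp and Gpc3 differed by 0.14 and 0.27 in the MYC tumours (adjusted p = 0.561 and 0.137) and by 0.09 and -0.06 in the MYC/REG3A tumours (adjusted p = 0.757 and 0.801). Glul and Alb differed by -1.16 and -0.09 in the MYC/REG3A tumours (adjusted p = 0.239 and 0.529). Xist differed by -0.06 in the MYC and -0.53 in the MYC/REG3A tumours (adjusted p = 0.915 and 0.385). In MYC/REG3A mice its change was -2.43 in mouse 1 and 0.229, 0.404 and -0.319 in mice 2, 3 and 4. Ogt and Oga, which add and remove O-GlcNAc, and Gfpt1, the entry enzyme of the hexosamine pathway, differed by -0.39, 0.16 and 0.19 in the MYC tumours (adjusted p = 0.0864, 0.39 and 0.548) and by -0.29, 0.16 and 0.18 in the MYC/REG3A tumours (adjusted p = 0.261, 0.441 and 0.63). The hexosamine list had no call in either tumour comparison (median 0.16 and -0.01, camera adjusted p = 0.379 and 0.929), although Uap1l1, Gnpda1 and Pgm3 rose in the MYC tumours by 0.89, 0.68 and 0.64 (SE 0.152, 0.231 and 0.155). Between genotypes its median was 0.03 in non-tumour liver (adjusted p = 0.371), -0.05 in tumours (adjusted p = 0.315) and -0.16 for the difference of the tumour changes (adjusted p = 0.0678). The antioxidant list had no call in the MYC tumours (median -0.25, adjusted p = 0.115), the MYC/REG3A tumours (median -0.01, adjusted p = 0.849), non-tumour liver between genotypes (median -0.08, adjusted p = 0.066) or tumours between genotypes (median 0.05, adjusted p = 0.285). It was called for the difference of the tumour changes (median 0.177, camera adjusted p = 0.0211; adjusted p = 0.722 with an estimated correlation). The 7 mouse REG family genes lay below the filter in all groups, with group means of 2.80 to 3.97, and were not tested.

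Clock genes spread widely between mice. The circadian list was not called in the MYC tumours (median -0.21, camera adjusted p = 0.221), the MYC/REG3A tumours (median -0.28, adjusted p = 0.0542), non-tumour liver between genotypes (median 0.16, adjusted p = 0.472) or tumours between genotypes (median 0.18, adjusted p = 0.548). Hlf and Per3 fell in the MYC tumours by 0.59 and 0.51 (SE 0.138 and 0.174, limma adjusted p = 0.00972 and 0.0464). In non-tumour liver the mean log2 level of Arntl, Clock and Npas2 was 7.48 in MYC mouse 4 and 7.9 in MYC/REG3A mouse 1 and 6.06 to 6.99 in the other 6 mice. The mean of Dbp, Tef, Hlf, Per1, Per3 and Ciart was 7.21 and 7.07 in these mice and 7.83 to 9.06 in the others. These 9 genes were chosen after the values of the 14 tested clock genes had been seen.

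**Figure D3:**
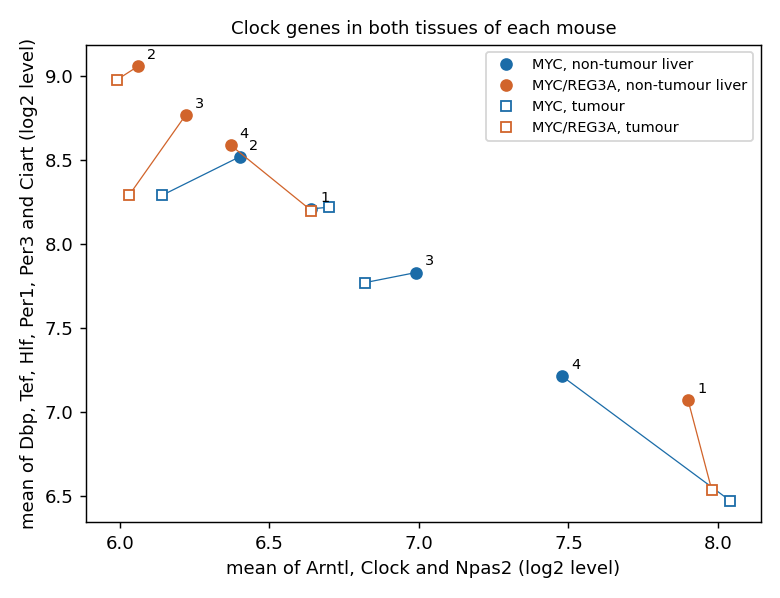
Mean log2 level of Dbp, Tef, Hlf, Per1, Per3 and Ciart against that of Arntl, Clock and Npas2 in non-tumour liver (circles, with the mouse number) and tumour (squares) of each mouse, joined by a line. In non-tumour liver MYC mouse 4 and MYC/REG3A mouse 1 lie at 7.48 and 7.9 on the horizontal axis, and the other 6 mice at 6.06 to 6.99.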

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

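The tests of mixed and diluted tissue, of exchanged samples and of genotype in this part were chosen after the results were seen, and the comparisons that gave the differences between genotypes were planned.

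In 12 of 187 groups of 4 arrays 1 array lay far from the other 3, a share near the 1 in 20 that chance gives. Several of these are female-biased sulfotransferases of MYC mouse 2. Sult2a2 had a log2 level of 8.26 in its tumour, against 3.66 to 4.29 in the other MYC tumours. Sult2a1 had 6.03 in the same tumour, against 2.5 to 2.62, and 9.8 in the non-tumour liver of that mouse, against 7.71 to 8.04. Gfpt1 was 7.11 in that tumour (others 6.43 to 6.53) and Ogt 9.52 in its non-tumour liver (others 9.71 to 9.73). In MYC mouse 3 Cyp4f15 was 9.61 in the tumour (others 8.91 to 8.98), Atp6v1e1 was 9.54 in non-tumour liver (others 9.7 to 9.71), and Reg3b and Reg3d, both below the filter, were 3.81 in the tumour (others 3.87 to 3.88) and 3.02 in non-tumour liver (others 3.2 to 3.21). In MYC/REG3A mice, Mup-ps12 was 7.17 in the tumour of mouse 2 (others 2.72 to 3.37), Ly6d was 8.16 there (others 10.4 to 10.6), and Ccnb2 was 5.05 in the non-tumour liver of mouse 1 (others 5.51 to 5.6).

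The tumour change differed between genotypes, by limma's direct test of the difference, in 1 gene, Trim43c, at -1.87 (adjusted p = 0.0412). By camera with the preset correlation it differed in 14 lists, and in 0 with an estimated correlation. The lowest of the 14 was then an adjusted p = 0.572 with an estimated correlation and the highest an adjusted p = 0.849 with an estimated correlation. As median differences of MYC/REG3A minus MYC, the lists were ribosome biogenesis at -0.295 (24 of 24 genes, adjusted p = 2.83e-07), oxidative phosphorylation at -0.22 (25 of 26, 0.000332), sinusoidal endothelium at 0.442 (16 of 16, 1.71e-07), female-biased genes at 1.3 (15 of 17, 6.76e-06), pericentral genes at 0.683 (19 of 19, 1.17e-05) and antigen presentation at 0.476 (13 of 14, 1.61e-05). Cytochrome P450 genes differed by 0.48 (25 of 30, adjusted p = 4.56e-05), with Cyp4f14 at 2.53 (SE 0.66), Ces1d at 1.28 (SE 0.247) and Cyp2c29 at 1.39 (SE 0.388). Stellate cell and matrix genes differed by 0.331 (18 of 21, adjusted p = 4.56e-05), with Dpt at 1.36 (SE 0.453), Hhip at 0.82 (SE 0.208) and Col6a3 at 0.75 (SE 0.198). Hhip lay below the lower quartile of every array in 3 MYC and 1 MYC/REG3A tumours, which limits what can be measured. Fatty acid oxidation differed by 0.329 (20 of 24, adjusted p = 0.000309), with Pdk4 at 1.30 (SE 0.488), and fatty acid synthesis by 0.343 (17 of 20, adjusted p = 0.00184). Bile duct markers differed by 0.256 (10 of 12, adjusted p = 0.0143), antioxidant genes by 0.177 (17 of 22, adjusted p = 0.0211), immediate early genes by 0.167 (14 of 21, adjusted p = 0.0272) and cholesterol synthesis by 0.181 (15 of 17, adjusted p = 0.0474). Single mice decided the calls of cholesterol synthesis (lost without MYC mouse 3 or 4 or MYC/REG3A mouse 2, 3 or 4), antioxidant genes (MYC mouse 1 or MYC/REG3A mouse 1 or 4), bile duct markers (MYC mouse 1 or MYC/REG3A mouse 2 or 3), immediate early genes (MYC mouse 1 or MYC/REG3A mouse 2 or 4), fatty acid synthesis (MYC mouse 2 or MYC/REG3A mouse 2), fatty acid oxidation (MYC mouse 2) and oxidative phosphorylation (MYC mouse 4). The call of Trim43c was lost without any 1 mouse except MYC/REG3A mouse 1. Without MYC/REG3A mice 2 and 4 the calls of cytochrome P450 genes (0.331), fatty acid oxidation (0.287) and antigen presentation (0.293) were kept, cholesterol synthesis was called in the opposite direction (-0.296), and the other 10 lists were not called. Their medians there were -0.125 for ribosome biogenesis, -0.0464 for oxidative phosphorylation, 0.133 for sinusoidal endothelium, 0.0304 for female-biased and -0.0116 for pericentral genes, 0.309 for stellate cell, 0.107 for fatty acid synthesis, 0.244 for bile duct, 0.163 for antioxidant and 0.0814 for immediate early genes.

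Of the 35 splits of the 8 mice into 4 and 4, 3 gave at least as many genes for this difference as the real one, which gave 1 (highest of the others 9), and 15 gave at least as many lists as the real 14 (highest 23), so chance cannot be excluded for either.

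The first pattern weighed is the smaller tumour change in MYC/REG3A mice 2 and 4, which carries part of these differences, as the medians without these mice show. An exchange of the samples of a mouse is argued against, since 30 of 31 cell cycle genes were higher in the tumour of mouse 2 and likewise 30 of 31 in mouse 4, and a tumour like the MYC tumours diluted with non-tumour liver is argued against as the whole cause in mouse 4, where 15 of 19 pericentral genes lay above all 8 non-tumour livers and all 4 MYC tumours (0 of 19 in mouse 2), the periportal median changed by -0.962 (lowest MYC tumour -0.399) and the cell cycle median of 1.44 lay within the 0.999 to 1.78 of the MYC mice. Some non-tumour liver in the tumour pieces cannot be told apart from a milder tumour or one of another kind, since the tumour shares rest on a MYC tumour profile: they were 41.7% from genes that rise in MYC tumours (95% interval 38.8 to 44.8) and 33.5% from genes that fall (30.5 to 37.2) in mouse 2, where 0 of 181 strongly falling genes fell by more than 2, and 35.8% (31.4 to 48.9) and 53.2% (46.4 to 57.1) in mouse 4, where 5 of 181 did. The intervals come from resampling genes within 1 mouse, and genes are not independent replicates. Those from risen and fallen genes also missed each other in MYC mice 3 and 4 and MYC/REG3A mouse 3. They overlapped in MYC mice 1 and 2 and MYC/REG3A mouse 1. A gap between the shares therefore does not decide on mixed tissue. The bound on falls by more than 2 replaced a rule on the overlap of the shares after these had been seen, because the shares rest on an assumed profile. The test of dilution was added later still. Under the first rule mixed tissue would have been set aside for mouse 2. An effect of the REG3A genotype stays open, since the SD of the change differed by -0.159 between genotypes with an exact permutation p of 0.143 (2-sided, 70 splits), and mice 1 and 3 changed as much as the MYC mice.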

How the results depend on the processing

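The fits without MYC/REG3A mice 2 and 4 and with clock genes as a covariate were chosen after the data were seen; the other alternatives were planned. Of the counts of genes under all alternatives 74 stayed within 1.5 times the reported count and 30 did not. For single genes 2070 values kept direction and side of the threshold, 99 lost the call, 30 gained it and 65 values without a call, of at most 0.992 in 9 genes, changed sign or, in 1 case, became 0. For called lists 888 kept both, 173 lost the call, 73 of these with an estimated correlation, and 7 reversed. Signal over background is unknown, so changes near the floor may be understated; the stricter filter left 4505 and 1690 within 1.5 times.

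A fold threshold of 1 gave 985 and 388 genes for tumour against non-tumour liver in MYC and MYC/REG3A mice, because it asks for larger changes. Leaving out 1 mouse gave 2975 (without MYC mouse 4) to 4490 in MYC mice and 273 (without MYC/REG3A mouse 3) to 1849 in MYC/REG3A mice, with 281 without mouse 1 and 944 without mouse 4. The clock covariate gave 232 in MYC/REG3A mice, 210 higher and 22 lower. Between genotypes, leaving out 1 mouse gave 0 to 22 (without MYC mouse 2) in non-tumour liver and 3 to 114 (without MYC/REG3A mouse 1) in tumours, with 21 without MYC mouse 2 and 13 without MYC mouse 3. In tumours the stricter filter gave 1, only the tumour arrays 0, the replicate block across genotypes 15, the clock covariate 8, and the fit without mice 2 and 4 gave 0. For the difference of the tumour changes, leaving out 1 mouse gave 0 to 2; no filter, the stricter filter, repeated quantile normalisation, no replicate block and the fit without mice 2 and 4 gave 0, and median centring and array weights gave 3 each. Except where fewer arrays or a fold threshold enter, the cause was not tested.

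Without mice 2 and 4 the medians that reversed were 0.00403 for interferon in non-tumour liver between genotypes, -0.111 for pericentral genes, -0.209 for fatty acid synthesis, -0.27 for cholesterol synthesis and -0.271 for sinusoidal endothelium in tumours between genotypes, and -0.0116 for pericentral genes and -0.296 for cholesterol synthesis in the difference of the tumour changes. Both values of cholesterol synthesis and that of sinusoidal endothelium were called in the reversed direction; the cause was not tested beyond the removal of these mice. The mouse numbers pair nothing across genotypes (correlations -0.271 to 0.415), so the block there is only an alternative. No replicate block in the tumour comparisons gave 4419 and 1613 genes, within 1.5 times. The planned covariate for sex was not run, since the sex-linked genes did not separate the mice.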

Other observations

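The tests of chance placement and of the genotype and phase of clock genes were chosen after their results were seen, while the control in non-tumour liver, the comparison of both parts of a chromosome and the splits of the samples were set before theirs. The tests of chromosome gain or loss and of noise in the clock list took the place of earlier ones after the patterns were known, and were set before their own results were seen.

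The p53 target Cdkn1a was among the clearest rises in the MYC tumours, although the list of p53 targets was not called in the tumours of either genotype against non-tumour liver. In the MYC tumours 7 of 17 tested p53 targets and senescence genes rose and 1 fell (median 0.28, camera adjusted p = 0.0642). Cdkn1a, the p21 inhibitor of the cell cycle, rose by 2.51 (SE 0.181, limma adjusted p = 0.000221) in tumours in which most tested cell cycle genes rose as well, Tnfrsf10b, a death receptor, by 1.89 (SE 0.273), Zmat3 by 1.35 (SE 0.265) and Phlda3 by 0.74 (SE 0.14). In the MYC/REG3A tumours 3 rose and 0 fell (median 0.09, camera adjusted p = 0.117), with Cdkn1a at 1.96 (SE 0.181), Tnfrsf10b at 1.56 (SE 0.273) and Gtse1 at 0.99 (SE 0.222). Of 20 genes of the integrated stress response and serine synthesis 5 rose and 2 fell in the MYC tumours (median 0.11, adjusted p = 0.247), among them Asns, the asparagine synthetase, by 2.57 (SE 0.54), Ddit4 by 0.96 (SE 0.129) and Trib3 by 0.75 (SE 0.141).

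Most female-biased genes passed as lower in the MYC tumours and fewer did in the MYC/REG3A tumours, and their list was called only with the preset correlation. The male-biased list was not called (median 0.33 and 0.56 in the MYC and MYC/REG3A tumours, camera adjusted p = 0.595 and 0.774), and its members went both ways. In the MYC tumours Cyp2d9, Selenbp2 and Cyp7b1 rose by 2.27, 1.92 and 1.05 (SE 0.52, 0.353 and 0.314) and Nudt7 fell by 1.15 (SE 0.129). Of 13 oncofetal and tumour markers 2 rose and 1 fell in the MYC tumours (median 0.42, adjusted p = 0.159), namely Tff3 by 1.82 (SE 0.607), Lpl, the lipoprotein lipase, by 1.74 (SE 0.292) and Cd24a, which fell by 1.43 (SE 0.402). In the MYC/REG3A tumours Lpl rose by 2.09 (SE 0.292) and Robo1 by 1.30 (SE 0.284), and the list was not called (median 0.31, adjusted p = 0.0978). Myc had its highest levels in MYC/REG3A mouse 2, at 9.24 in non-tumour liver and 9.37 in the tumour, against 6.84 to 7.97 on the other 14 arrays; this mouse was singled out after its values were seen.

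The second pattern weighed is a shift of whole chromosomes in the tumours, with 13527 genes placed by the RefSeq table. The median change of a chromosome is given relative to the tumour's own median over all these genes. It was above 0 in all 8 tumours on chromosomes 15 (0.124 to 0.378), 16 (0.0625 to 0.604) and 3. It was below 0 in all 8 on chromosomes 14 (-0.39 to -0.0302), X (-0.348 to -0.0587), 8 and 17. Of 160 pairs of a tumour and a chromosome, 50 differed from the other 7 tumours by at least 0.1. Examples are chromosome 16 in MYC/REG3A mouse 3 (0.379), chromosomes 1 and 13 in MYC mouse 4 (0.265 and 0.264) and chromosome 18 in MYC mouse 2 (0.238). Chance placement is argued against, as 0 of 100 random reassignments gave as many pairs (highest 0). So is a regional effect shared with non-tumour liver (0 pairs). One in tumours alone was untested. Local clusters of genes are argued against for most pairs, since both parts of a chromosome, split at its middle gene, moved the same way, each by over 50% of the whole shift, in 46 of 50 pairs (92%), an exception being chromosome 3 in MYC mouse 1, whose parts lay at 0.418 and -0.208. Gain or loss of whole chromosomes may account for the pattern but could not be separated from other changes of expression. With only the 8871 genes called in neither comparison of tumour with non-tumour liver, 45 of the 50 pairs (90%) kept their direction and over 50% of their shift. These genes are among those that chose the pairs, and a change in a single tumour need not be called in its group. The share therefore does not decide the question. In MYC/REG3A mice 2 and 4 part of the shift against the other tumours reflects their smaller change, as on chromosome 14, where mouse 2 lay at -0.0785 relative to its own median. No DNA was measured.

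The third pattern weighed is the spread of clock genes between mice, seen when a regrouping of the tumours gave more genes than the genotypes did. Noise of single arrays is argued against, since over the 14 tested genes of the preset circadian list the levels in non-tumour liver and tumour of the same mouse had a median r of 0.846 (8 mice, 13 genes above 0, exact permutation p = 0.000124, 1-sided; median rho = 0.679; median r = 0.632 without MYC mouse 4 and MYC/REG3A mouse 1, the 2 farthest in the output genes). Genotype as the whole cause is argued against, since the mean of 6 output genes minus that of 3 activator genes in non-tumour liver differed by 0.668 between genotypes (exact permutation p = 0.514, 2-sided) and ranged over 2.39 and 3.83 within them. Tissue taken at different times of day stays a candidate explanation that cannot be told apart from others, since collection times are not given and the opposition of activator and output genes was found on genes picked to show it. In 4 list genes outside both groups, Cry1 and Nfil3 taken as opposed to the output genes and Nr1d1 and Nr1d2 as moving with them, the mean signed r with the output genes was 0.187 in non-tumour liver (8 mice, exact permutation p = 0.558, adjusted over 2 relations p = 0.558; rho 0.286; 0.677 without the 2 farthest mice), with Cry1, Nfil3, Nr1d1 and Nr1d2 at r = 0.31, -0.547, -0.256 and 0.766 (Cry2, of no clear phase, 0.908), and 0.672 in tumours (exact p = 0.0187, adjusted p = 0.0375; rho 0.536; 0.297 without the 2 farthest), which rests on those mice.

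Markers of 9 other cell types in the non-tumour liver of MYC/REG3A mice were also pooled, and the clock genes took their place among the weighed patterns after the splits of the samples had been seen. The 115 markers had a pooled median difference of -0.333 (95% interval -0.393 to -0.274). The intervals here come from resampling the markers, which are not independent replicates, so they do not measure the spread between mice. The pooled median includes the lists set against it. In 2 of the 9 lists, T cell markers (-0.0859, interval -0.229 to -0.00445) and B cell markers (-0.037, interval -0.274 to 0.0767), the interval lay above the pooled median. In 3 of the 9 it lay below the pooled median: neutrophil markers (-0.458, interval -1.14 to -0.391), stellate cell and matrix genes (-0.446, interval -0.511 to -0.394) and macrophage markers (-0.427, interval -0.494 to -0.335). The upper ends for neutrophil and macrophage markers lay within the pooled interval.

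Among the 35 splits of the 8 arrays of a genotype into 4 and 4, without the mouse block, only the real one, 1 of 35, gave as many genes as tumour against non-tumour liver in MYC mice (4419, highest of the others 6) and likewise 1 of 35 in MYC/REG3A mice (1613, highest 12). These splits ignore the pairing of samples within a mouse, and all but the real one mix tumour and non-tumour liver in both arms. They therefore do not exclude chance by themselves. Among the 8 splits that part every pair of a mouse, with the block, which are too few for a share under 0.05, the real ones gave 4505 and 1690 genes and the highest of the others 0 in both, so that 1 of 8 reached the real count in each; the others mix tumour and non-tumour liver in each arm. Between genotypes in non-tumour liver the real count was 0 genes, which all 35 splits reach by construction (highest other 5), so that they test nothing there, and 13 of 35 gave at least the real 14 lists (highest other 17). In tumours 12 of 35 gave at least the real 3 genes, and 15 at least the real 13 lists (highest other 18). Chance cannot be excluded for the lists in either tissue or for the genes in tumours. The highest of the other splits of the tumours gave 334 genes, a structure of the samples. It set the tumours of MYC mice 1, 3 and 4 and MYC/REG3A mouse 1 against the rest. This is the genotype split with only MYC mouse 2 and MYC/REG3A mouse 1 exchanged, and it follows no batch in the labels. The same exchange gave the most genes, 9, for the difference of the tumour changes. The genotype labels could not be checked on their gene. On the second principal component these 4 mice lay at 14.9 to 17.4 in non-tumour liver (others -18 to -1.01) and at 3.52 to 14.6 in tumours (others -22 to -3.54). These 4 mice had the lowest output minus activator clock levels, at -1.57 to 1.52 in tumours (others 1.56 to 2.99) and -0.826 to 1.58 in non-tumour liver (others 2.12 to 3), over 9 genes picked after being seen.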
